A study of Rangifer tarandus with 8 samples.

How the data were processed

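The series holds 8 droplet single-cell RNA libraries from adult reindeer (Rangifer tarandus), 1 for each combination of tissue (skin covering the growing antler, called velvet, and back skin) and day (0, 3, 7 and 14). Day 0 is uninjured skin, and the other days follow a circular full-thickness excision, per the labels. Per the labels' protocols, excised skin was treated with dispase to remove the epidermis, the dermis was digested with collagenase, dead cells were gated out by scatter and a viability dye, and the sorted cells were loaded on the 10x Genomics 3′ version 3 chemistry. The dispase step and the sort gate set part of every share of cells given here. The labels do not tie libraries to animals, so each tissue and day is 1 library with no replicate, and p-values measure only the spread between these libraries, part of which may be technical.

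The deposited matrices hold raw UMI counts per gene and cell barcode, not normalized. Per the file headers they were written by Cell Ranger, and the submitters' processing notes list Cell Ranger 3, STAR and Seurat 3.1.1. Per the labels, reads were aligned to a bovine reference made with the Cell Ranger reference builder. The deposited annotation names the bovine assembly ARS-UCD1.2 and Ensembl identifiers. The STAR version and alignment settings are not given in the sources used here. Reindeer reads aligned to a cattle genome can be lost or misassigned where the species differ, and both tissues share that limit. The files list 21880 genes, of which 5070 have no symbol. The number of barcodes per library equals the number of recovered cells in the labels, and every barcode has at least 500 UMIs, so a UMI filter at that level had been applied before deposit. The deposited files carry no cell type annotation.

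Barcodes were kept with at least 500 UMIs, at least 250 genes and at most 15% mitochondrial UMIs. Doublets were scored with Scrublet in scanpy 1.11.5. Its own threshold called between 0 and 3 barcodes per library, which is no working call, so the highest-scoring barcodes were removed at a fixed 0.8% for every 1000 barcodes left in the library. That left 49547 cells. The 2000 most variable genes, ranked within libraries, gave 30 principal components. A graph of 15 nearest neighbours was weighted by shared neighbours, with at least 3 shared, and divided by the Leiden algorithm at resolution 1 with seed 0, which gave 40 clusters. Clusters were named from marker lists fixed before the data were examined. A marker counted where some cluster reached 50 CPM (counts-per-million of UMIs within the cluster). It was present in a cluster at 0.25 or more of its highest cluster. A class needed at least 3 present markers, a mean relative level of at least 0.25 (0.15 with a marker among the top 10 genes by fold, with a pseudocount of 10 CPM) and a margin of 1.5 over the next class. Clusters whose median UMI count lay under their library's divided by 3, with no class marker among the top 10 genes, stayed unnamed. These thresholds and the shared-neighbour graph replaced a first version (level 0.15, margin 1.25, 31 clusters) after its clusters had been looked at and before any gene was tested. The change moved a cluster led by IL1B into the macrophage/monocyte class, which went from 1969 to 4752 cells. Results with the first version are in the closing section. All class names are rebuilt from markers, so each class is written as a "like" class and a different naming would move its values.

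For each library and class with at least 20 cells, raw UMI counts were summed over cells. Sums for fibroblast-like, macrophage/monocyte-like, blood endothelial-like and mural-like cells in all 8 libraries were tested with edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest, TMM normalization, filterByExpr, day as a factor and tissue, 3 residual degrees of freedom). The tissue effect is velvet over back averaged over the 4 days, and its spread is the variation of that difference between days. Each later day was compared with day 0 in the same fit, averaged over the tissues, with 2 libraries per day. A separate term in fibroblast-like cells tested whether the tissue difference in wounds differed from that in uninjured skin, with 2 residual degrees of freedom. Adjusted p-values are Benjamini-Hochberg values within a comparison, with a threshold of 0.05. A standard error is the size of the log2 fold change divided by the square root of the F statistic. CPM values are scaled by the class total of a library, without TMM factors. On counts simulated from these libraries, 200 genes with a mean of at least 20 CPM were changed by folds of 2, 4, 8 and 16. Each gene's spread between libraries was set to the trend of genes at its level. All genes changed by 4, 8 or 16 were called in each class, and 50.0%, 32.0%, 44.0% and 32.0% of those changed by 2 in the fibroblast, macrophage/monocyte, endothelial and mural fits, which ran on 11833, 9749, 9858 and 6640 genes.

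Gene lists, also fixed beforehand, were tested with camera in limma 3.58.1 at a preset correlation of 0.01, two-sided, adjusted over the lists of a comparison. The lists, with the members in the file, were inflammatory mediators (37), complement and acute phase (19), interferon response (25), antigen presentation (15), fibrillar collagen and elastic matrix (41), myofibroblast and contractile (22), matrix proteases and inhibitors (29), TGF-beta and activin (29), BMP (24), WNT (39), fetal-like and dermal development (36), retinoid pathway (21), HOX genes (35), cranial mesenchyme and neural crest (29), IGF, androgen and growth factor axis (37), angiogenic factors (26), hypoxia and glycolysis (24), cell cycle (30), dissociation and immediate early genes (30), macrophage inflammatory (31), macrophage resolution and tissue resident (30), lipid handling (17) and an erythrocyte marker check (4). Several lists share members. No camera call in any comparison held with a correlation estimated from the data. In 31 of the 243 list results the median, the mean and the camera direction differed in sign, and the smallest camera adjusted p among those was 0.391.

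Genes are named by a rule fixed beforehand. Between tissues it takes the 12 genes per direction in fibroblast-like cells, and 6 in other classes, with the largest absolute log2 fold change among genes past the threshold, with a mean of at least 20 CPM, the same direction on every day and a symbol. Day contrasts take 8 genes per direction for fibroblast-like and 5 for macrophage/monocyte-like cells, with the same direction in both tissues. Each list gives up to 4 members with the smallest p. Ribosomal protein, mitochondrial and immunoglobulin genes were left out. Some genes that the rule or the lists took are not reported here. Within a single day the libraries cannot be tested. For each class and day, the 6 genes per direction with the largest CPM ratio were taken among genes with at least 100 UMIs in the higher library and a mean of at least 20 CPM. Their intervals are 95% exact Poisson intervals of the ratio, and 0 UMIs were replaced by a floor of 3 counts. On simulated pairs of fibroblast-like libraries at day 3, run on 21880 genes, between 47 and 48 of 50 such intervals covered the simulated ratio at each fold. Shares of cells carry 95% exact binomial (Clopper-Pearson) intervals. Both kinds of interval cover counting error only. For a list within 1 day, the median log2 ratio of members with a mean of at least 5 CPM was ranked among 10000 random lists of the same size drawn from 20 bins of expression. Random lists do not allow for members that move together, so these percentiles are not tests.

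Alternatives set beforehand were RLE normalization, the DESeq2 1.42.0 Wald test, no filter beyond 1 UMI, a filter of 20 mean CPM, a stricter cell filter (1000 UMIs, 500 genes, 10% mitochondrial UMIs), doublets kept, a clustering resolution of 2, equal numbers of cells per library, no day covariate, each day pair or library left out, other denominators for shares, other scalings for single-day ratios, an estimated correlation and the fry test for lists. Alternatives added after seeing the data were the first clustering version, leaving out clusters of which 1 library held over 80% of the cells, and 2 other makeups of the macrophage/monocyte class. Tables of how many cells carried a named gene's UMIs were also added after seeing the data. Cells in the 15 unnamed clusters entered no main test of genes. Those of cluster 14 were added to the macrophage/monocyte class in the alternative with the close unnamed clusters.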

Results

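The series was designed to compare wound healing in reindeer antler velvet, which its labels call regenerative, with that in back skin, called non-regenerative. Cells were profiled from both before injury and 3, 7 and 14 days after a circular excision, with 1 library per site and day. The matrices held 5620, 11004, 6520 and 9719 barcodes for velvet at days 0, 3, 7 and 14, and 9006, 6287, 4112 and 2760 for back skin. Total UMI counts ran from 28293328 in back skin at day 7 to 65966271 in velvet at day 3. The median barcode held 3255, 4038.5, 1337 and 4039 UMIs in velvet and 3763, 4504, 3057 and 7455 in back skin at the same days. Velvet at day 7 was lowest, with 43.9% of its cells in low-UMI cluster 0. After filtering, 5288, 9849, 5433 and 8941 velvet cells and 8225, 5796, 3415 and 2600 back cells remained.

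The 6 fibroblast-like clusters together held 7657 cells. Cluster 4 was led by DPEP1, THBS4 and APOD. Cluster 10, led by MFAP5, CHRDL1, SCARA5 and MYOC, came almost wholly from uninjured back skin (1526 of 1553 cells). Cluster 15 (SFRP2, ASPN, SFRP4 and CA3) had 280 velvet and 5 back cells at day 0. Cluster 22, led by SLPI, ACTG2, FN1 and CTHRC1, was a wound cluster. Cluster 26 (COCH and PTGDS) had 562 of its 600 cells from uninjured back skin. Cluster 29, led by HP, CHI3L1, CCL19 and IL6, had 331 of its 385 cells from back skin at day 3, and HP, CCL19 and IL6 are acute phase and immune genes. Clusters 10, 26 and 29 came mostly from 1 library each, so library and cell type cannot be told apart there. In velvet, clusters 4 and 15 held 62.2% and 36.5% of fibroblast-like cells at day 0, and cluster 22 held 58.0% at day 7. In back skin, cluster 10 held 47.8% at day 0, cluster 29 held 57.5% at day 3, cluster 22 held 62.4% at day 7, and cluster 15 held 46.7% at day 14.

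Macrophage/monocyte-like cells comprised cluster 3 (3018 cells, led by IL1B, NLRP3, CCL3, IL10 and IL1RN, with none of the class markers among its top 10 genes), cluster 11 (1542 cells, led by C1QA, C1QB and C1QC) and cluster 33 (CCL24, FOLR3 and LYVE1, with 168 of 192 cells from uninjured back skin). Cluster 3 held 93.0% of this class in back skin and 65.0% in velvet at day 3, cluster 11 held 66.0% in uninjured velvet, and cluster 33 held 80.4% in uninjured back skin. Blood endothelial-like cells (clusters 1, 24 and 34), mural-like cells (cluster 21, led by APOE, DES, MYH11 and RGS5), lymphatic endothelial-like, T and NK-like, mast-like, dendritic-like and keratinocyte-like cells were also named. The 15 unnamed clusters held 38.0%, 34.1%, 62.9% and 15.5% of velvet cells and 15.5%, 43.7%, 47.0% and 14.7% of back cells at days 0, 3, 7 and 14. They included cluster 0, led by CATHL3, TNFSF14 and C5AR1, with neutrophil as its closest class and a median of only 680 UMIs. It made up 5.87% and 43.9% of velvet and 21.3% and 27.5% of back cells at days 3 and 7. They also included cluster 14, led by the defensin genes defb402 and LAP with PTX3 and SAA3, closest to macrophages, at 3.50% of velvet and 11.3% of back cells at day 3.

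Fibroblast-like cells made up 38.8% of cells in uninjured back skin (95% exact interval 37.8 to 39.9) and 14.5% in uninjured velvet (13.6 to 15.5). In wounds their share was 9.03%, 10.8% and 9.88% in velvet and 9.94%, 10.5% and 15.6% in back skin at days 3, 7 and 14. Macrophage/monocyte-like cells were 1.83% of velvet and 2.54% of back cells before injury, then 9.17%, 7.66% and 6.11% in velvet against 26.9%, 19.1% and 14.3% in back skin. As named here their share was lower in velvet on 4 of 4 days. In the first clustering version, which left the IL1B-led cluster out, it was 1.38%, 4.23%, 3.59% and 3.48% in velvet against 2.41%, 4.05%, 8.61% and 9.46% in back skin, lower on 3 of 4 days. With only the clusters led by class markers it was 3.21% against 1.88% at day 3, higher in velvet, and without cluster 33 it was higher in velvet before injury (1.72% against 0.498%). Dendritic-like cells had a lower share in velvet on 4 of 4 days (1.06%, 1.44%, 1.42% and 2.26% against 3.10%, 2.73%, 4.92% and 8.69%). For both classes the exact two-sided sign-flip permutation test over the 4 day pairs gave the smallest value it can give, 2 of 16 sign patterns, so no share could pass 0.05. T and NK-like cells were 3.64%, 1.73%, 7.09% and 15.4% of back cells at days 0, 3, 7 and 14 and 6.68%, 3.08%, 2.15% and 3.17% of velvet cells (exact permutation p = 0.5). With only immune cells as the denominator, the sign of that difference turned (mean logit difference 0.21 against -0.43). Keratinocyte-like cells were 14.7%, 19.6%, 7.49% and 47.1% of velvet and 22.7%, 7.06%, 1.61% and 8.65% of back cells at days 0, 3, 7 and 14, after a dispase step meant to remove epidermis (exact permutation p = 0.25). Mast-like cells were 7.05%, 3.89%, 0.957% and 3.09% of velvet and 4.62%, 0.690%, 1.02% and 1.00% of back cells (exact permutation p = 0.25). Without the clusters held by 1 library, the sign for fibroblast-like cells turned (mean logit difference 0.17 against -0.48). The exact permutation p was 0.25 for fibroblast-like, 0.5 for blood endothelial-like, 0.625 for lymphatic endothelial-like and 1.0 for mural-like cells. The sign for mural-like cells (mean logit difference 0.03) and lymphatic cells (-0.51) turned when 1 day pair was left out, to -0.0605 for mural-like without day 3, -0.0542 without day 7, and 0.0568 for lymphatic without day 14.

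**Figure D1:**
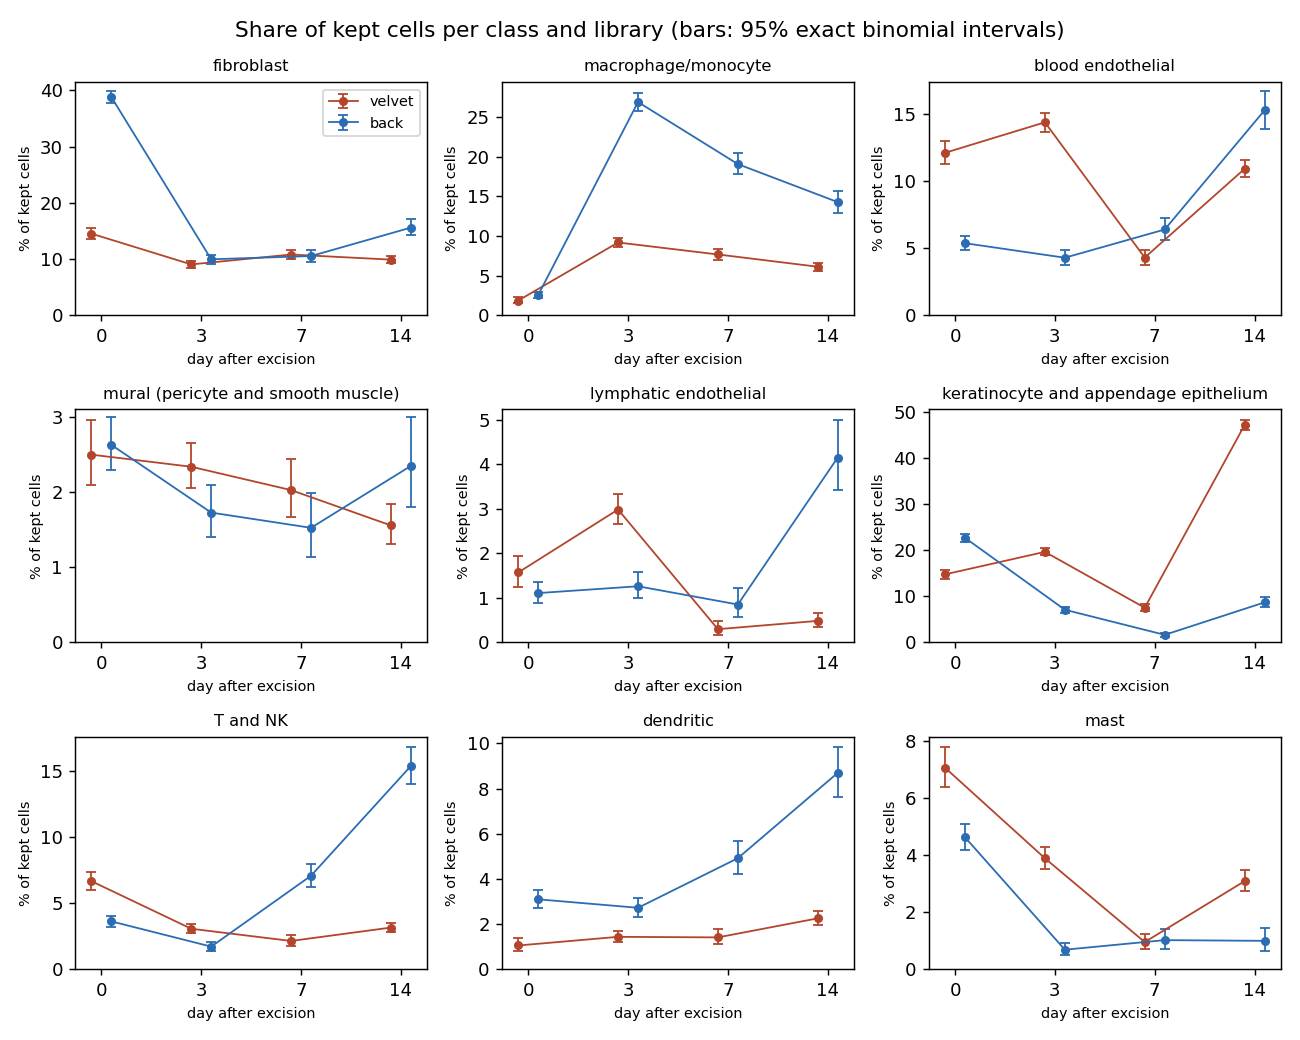
Share of kept cells (%, vertical axis) in each named class against day after excision (horizontal axis), for velvet (red) and back skin (blue), with 1 library per point and bars showing 95% exact binomial intervals for counting error. Macrophage/monocyte-like cells as named here stand at 26.9% in back skin and 9.17% in velvet at day 3, and in the first clustering version, not drawn, at 4.05% and 4.23%.

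Between fibroblast-like cells of velvet and back skin, 366 of 12024 genes passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, of which 179 were higher and 187 lower in velvet. Velvet cells had higher CA3 (carbonic anhydrase 3; log2 fold change 5.87 ± 0.54, SE), PTN (pleiotrophin, a heparin-binding growth factor; 5.42 ± 0.75), BMP3 (an inhibitory bone morphogenetic protein; 3.86 ± 0.29) and CNN1 (calponin, a contractile protein; 2.94 ± 0.29). Back cells had higher PTGDS (prostaglandin D2 synthase; -7.79 ± 1.02), HP (haptoglobin, an acute phase protein; -6.65 ± 0.49) and CSF3 (the granulocyte growth factor G-CSF; -5.09 ± 0.46). Each of these genes differed in the same direction on 4 of 4 days (n = 8 libraries).

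Among genes with a mean of at least 20 CPM and the same direction on every day, those with the largest changes were as follows, with positions on the ARS-UCD1.2 assembly and HOX genes given apart. CA3 (ENSBTAG00000015214, chromosome 14, 77028978 to 77038971; edgeR adjusted p = 0.00464) was measured at 81.0, 11.02, 16.4 and 57.9 CPM in velvet and at 0.513, 0.521, 0.609 and 0.215 CPM in back skin at days 0, 3, 7 and 14. PTN (ENSBTAG00000002317, chromosome 4, 100885905 to 100995239; adjusted p = 0.0159) was at 1814, 336, 129 and 2234 CPM in velvet and between 6.45 and 27.4 CPM in back skin. SST, the hormone somatostatin (ENSBTAG00000017312, chromosome 1, 79657444 to 79659377), was higher in velvet by 5.76 ± 0.62 (adjusted p = 0.00665), and PPFIA2, a liprin (ENSBTAG00000003036, chromosome 5, 10849058 to 11349736), by 5.61 ± 0.24 (adjusted p = 0.000354). APOA1, the main apolipoprotein of HDL (ENSBTAG00000002258, chromosome 15, 27490875 to 27505442), was higher by 4.59 ± 0.37 (adjusted p = 0.00268), and BMP3 (ENSBTAG00000017642, chromosome 6, 95815372 to 95844458) had an adjusted p of 0.00199. SORBS2 (3.34 ± 0.34), the serum amyloid gene M-SAA3.2 (3.14 ± 0.37), CCDC68 (2.96 ± 0.47), GSC (the homeobox gene goosecoid; 2.76 ± 0.46) and WFDC1 (2.69 ± 0.45) completed the 12 highest. On the lower side, HP (ENSBTAG00000006354, chromosome 18, 39037402 to 39043531; adjusted p = 0.00199) stood at 1.42, 77.4, 7.38 and 8.67 CPM in velvet and 36.4, 4160, 1226 and 1169 CPM in back skin.

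PTGDS (ENSBTAG00000015074, chromosome 11, 106021670 to 106024967; edgeR adjusted p = 0.0128) was at 2089 CPM in uninjured back skin and at 0.474 to 1.64 CPM in the 4 velvet libraries. CSF3 (ENSBTAG00000021462, chromosome 19, 40330599 to 40332907) had an adjusted p of 0.00464. MYOC (myocilin, -6.86 ± 0.87), TCF21 (a mesenchymal transcription factor, -5.78 ± 0.66), TNFAIP6 (a hyaluronan-binding protein induced by inflammation, -3.42 ± 0.35), the chemokines CCL20 (-3.32 ± 0.63) and CXCL3 (-3.21 ± 0.50) and RARRES2 (chemerin, -3.18 ± 0.21) were also lower in velvet. A few cells carried much of the signal of some genes. The top 1% of cells held 85.3% of the APOA1, 72.5% of the SST, 50.2% of the CA3 and 36.6% of the PTN UMIs of velvet, and 80.1% of the CCL20, 64.5% of the HP and 59.5% of the CSF3 UMIs of back skin. Under a stricter filter most cells rich in APOA1 (49 of 61), CA3 (17 of 18) and PTN (223 of 260) joined an unnamed cluster. Of its 307 cells 301 were from velvet. Its leading genes included SFRP2, CA3, PTN, APOA1 and PPFIA2, for which cell subtype and tissue were not told apart. The difference was then 3.11 for CA3 and 2.67 for PTN, both past the threshold, and 0.48 for APOA1 (adjusted p = 0.819). CNN1 was then at 2.31 (adjusted p = 0.0929). Over all alternatives 0.819 and 0.0929 were the highest adjusted p of APOA1 and CNN1. Of the named genes only CA3, PPFIA2 and HOXC8 passed in every alternative. With no day covariate only these and PTGDS kept their call, of the 23 then tested.

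The number of genes past the threshold depended on single days, at 198, 68, 153 and 198 genes without the libraries of day 0, 3, 7 or 14. Without day 3, PTN, CCDC68, GSC, WFDC1, PTGDS, CCL20 and CXCL3 no longer passed, and without day 0, PTN, GSC, WFDC1, MYOC and CCL20 did not. GSC, CCL20 and CXCL3 did not pass without day 14, nor CCDC68 and WFDC1 without day 7. Leaving out the clusters held by 1 library (clusters 10, 26, 29 and 33) gave 90 genes, and PTGDS, CSF3, CXCL3, CCDC68, GSC and WFDC1 were among those that no longer passed.

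**Figure D2:**
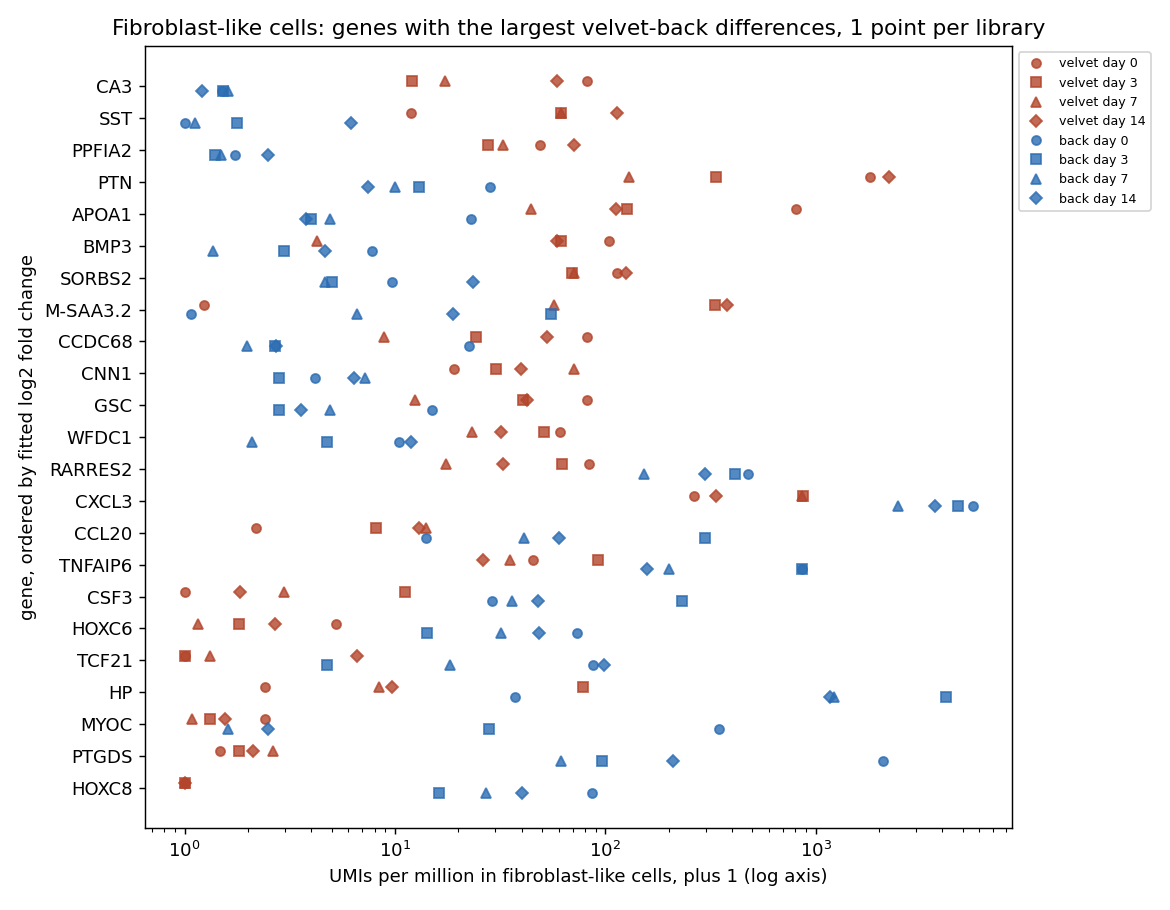
CPM plus 1 (log axis, horizontal) of 23 genes with the largest velvet-back differences in fibroblast-like cells (vertical axis), with 1 point per library, red for velvet and blue for back skin, and the marker shape giving the day. HP runs from 1.42 to 77.4 CPM in velvet and from 36.4 to 4160 CPM in back skin.

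Inflammatory mediators were lower in velvet fibroblast-like cells: 0 of 36 measured members were higher, 9 were lower (21 lower when adjusted over the list alone) and 27 did not pass. Camera gave an adjusted p of 1.25e-10 (adjusted p = 0.29 with an estimated correlation). Beside CSF3 and TNFAIP6, these included the monocyte attractant CCL2 (-2.32 ± 0.27) and CXCL12 (-1.76 ± 0.21). Complement and acute phase genes were lower in 6 of 17 (10 adjusted over the list alone; camera adjusted p = 2.04e-08; adjusted p = 0.155 with an estimated correlation). C7 stood at -4.22 ± 0.28, C3 at -2.98 ± 0.43 and C2 at -2.23 ± 0.34. The macrophage inflammatory list, which shares members with the first, had 6 of 28 lower and none higher (13 lower adjusted over the list alone; camera adjusted p = 7.28e-10; adjusted p = 0.29 with an estimated correlation). PTGS2 (-2.97) and S100A8 (-2.11) were among them. Hypoxia and glycolysis genes had 3 of 23 lower (6 adjusted over the list alone; camera adjusted p = 2.6e-06; adjusted p = 0.29 with an estimated correlation). Among them were SLC2A3 (-1.92) and PFKFB3 (-1.72). Immediate early and dissociation genes had 2 of 29 lower, IER3 (-2.06) and KLF4 (-1.52), 4 adjusted over the list alone (camera adjusted p = 6.85e-05; adjusted p = 0.399 with an estimated correlation).

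Contractile genes were higher in velvet: 6 of 22 passed, all higher (17 adjusted over the list alone; camera adjusted p = 4.55e-11; adjusted p = 0.29 with an estimated correlation). They included LRRC15 (2.66), TPM1 (tropomyosin, 1.76) and LMOD1 (1.62). Fetal-like and dermal development genes were higher in 6 of 34 and lower in none (15 and 2 adjusted over the list alone; camera adjusted p = 2.6e-06; adjusted p = 0.155 with an estimated correlation). They included PTN, LEF1 (1.96), FREM1 (2.74) and MDK (midkine, 1.61). WNT genes were higher in 5 of 32 and lower in 1 (9 and 1 adjusted over the list alone; camera adjusted p = 0.000159; adjusted p = 0.379 with an estimated correlation). They included the WNT inhibitors APCDD1 (2.49) and DKK3 (1.61), the ligand WNT16 (2.11) and the WNT-responsive factor LEF1. Interferon genes had 1 of 20 higher, IRF9 (0.87), and a camera adjusted p of 0.000749 (adjusted p = 0.29 with an estimated correlation), and antigen presentation genes 0 of 11 with a camera adjusted p of 0.0489 toward back skin (adjusted p = 0.328 with an estimated correlation).

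Other lists than these and the HOX genes did not pass camera. Cranial mesenchyme and neural crest genes had 4 of 20 higher (5 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.11). These were ALX1 (7.25 ± 0.48), DLX6 (5.74 ± 0.53), DLX5 (3.39 ± 0.38) and TFAP2A (1.76 ± 0.33), all transcription factors of the embryonic head. BMP genes had 2 of 21 higher, BMP3 and SOSTDC1 (2.15), and 1 lower, CHRDL1 (-2.72; camera adjusted p = 0.062). Collagen and elastic matrix genes had 3 of 41 higher and 2 lower (6 and 4 adjusted over the list alone; camera adjusted p = 0.088), with COL11A1 (2.52) and COL12A1 (1.60) higher and MFAP5 (-3.08) and THBS1 (-1.35) lower. Growth factor axis genes had 2 of 35 higher and 3 lower (camera adjusted p = 0.315), with the estrogen receptor ESR1 (2.66) higher and EREG (-4.38) and FGF7 (-1.56) among the lower. Angiogenic factors had 4 of 24 lower, including VEGFD (-5.13) and SEMA3C (-2.37; camera adjusted p = 0.088). Proteases had 1 higher and 2 lower of 28 (camera adjusted p = 0.109), lipid handling 1 and 2 of 16 (0.676), the retinoid pathway 1 and 1 of 17 (0.734), TGF-beta and activin 0 and 1 of 28 (0.835) and macrophage resolution genes 0 and 1 of 22 (0.856). No cell cycle gene passed of 30 (0.174).

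HOX genes, which mark position along the body axis, were far lower in velvet. Of 17 tested in fibroblast-like cells, 14 were lower and none higher (15 lower and 1 higher adjusted over the list alone; camera adjusted p = 2.73e-17; adjusted p = 0.29 with an estimated correlation). HOXC8 (ENSBTAG00000012149, chromosome 5, 26020286 to 26023408) had 0 UMIs in the 4 velvet libraries together and 1676 in back skin, at least 428-fold lower against a floor of 3 counts over the velvet group. HOXC6 (ENSBTAG00000009238, chromosome 5, 26002104 to 26016051) had 31 against 1560 UMIs (-5.13 ± 0.47, adjusted p = 0.00464). In all, 8 of the 17 had 0 velvet UMIs, and the list's median log2 fold change was -7.14 as fitted and -4.96 with those genes at their bounds. The exceptions were HOXD1 (0.49, 53 against 48 UMIs), HOXD4 (1.37, 281 against 138 UMIs) and HOXD8 (-1.83, 12 against 58 UMIs), which did not pass over all genes.

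Blood endothelial-like cells of velvet also had lower HOX genes. Of 18 tested, 8 were lower in velvet and none higher (12 lower adjusted over the list alone; camera adjusted p = 1.12e-19; adjusted p = 0.127 with an estimated correlation). HOXB7 (ENSBTAG00000005546, chromosome 19, 37882057 to 37885440) was lower by -6.10 ± 0.40 (adjusted p = 0.00298), at 0.180 to 1.52 CPM in velvet and 41.5 to 62.5 CPM in back skin. In all, 6 of the 18 had 0 velvet UMIs, and the median was -6.01 as fitted and -4.65 with those at their bounds. HOXD1, HOXD3, HOXD4, HOXD8, HOXD9 and HOXD10 lay between -0.66 and 0.57 and did not pass. Velvet endothelial cells also had lower CD36 (a fatty acid receptor, -4.63 ± 0.64), CSF3 (-4.51 ± 0.69), IL6 (-4.08 ± 0.61), AMIGO2 (-3.74 ± 0.49) and SCIN (scinderin, -3.70 ± 0.50), and higher TNC (tenascin C, 2.00 ± 0.27), GNG2 (1.94 ± 0.20), PKDCC (1.34 ± 0.20) and MALL (1.16 ± 0.19). All these ran the same way on 4 of 4 days. In edgeR, 55 of 10103 genes passed, 18 higher and 37 lower in velvet.

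Contractile and myofibroblast genes were higher in velvet endothelial cells in 3 of 19, or 4 adjusted over the list alone. Camera gave an adjusted p of 3.69e-06 (adjusted p = 0.127 with an estimated correlation). The 3 were ACTA2 (smooth muscle actin, 2.69 ± 0.32), TNC and CTHRC1 (2.23 ± 0.34). ACTA2 is also a leading gene of mural-like cluster 21, and CTHRC1 of fibroblast-like cluster 22. Whether RNA of those cells gave these differences was not tested. Inflammatory mediators were lower in 3 of 32 (13 lower and 2 higher adjusted over the list alone; camera adjusted p = 0.000221; adjusted p = 0.541 with an estimated correlation), and the macrophage inflammatory list in 2 of 26, IL6 and SOD2 (-1.83; camera adjusted p = 0.00152; adjusted p = 0.35 with an estimated correlation). Interferon genes (0 of 23; camera adjusted p = 0.000113) and collagens (0 of 27; 0.0127) tested higher in velvet with no member past the threshold (adjusted p = 0.656 and adjusted p = 0.477 with an estimated correlation). Lipid handling had 3 of 16 lower, PLIN2 (-2.85), CD36 and FABP5 (-1.53; camera adjusted p = 0.0524). Complement had 1 higher, CFI (1.90), and 1 lower, HP (-4.03), of 12. The count of 55 genes was 12, 5, 1 and 40 without day 0, 3, 7 or 14. Of the 10 named genes 9 did not pass without day 3 and 9 without day 7, the exception in both being HOXB7. The keratin KRT14 was at 395.5 and 499.8 CPM in velvet endothelial cells at days 3 and 14 and at 75.6 and 187 CPM in back cells.

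**Figure D3:**
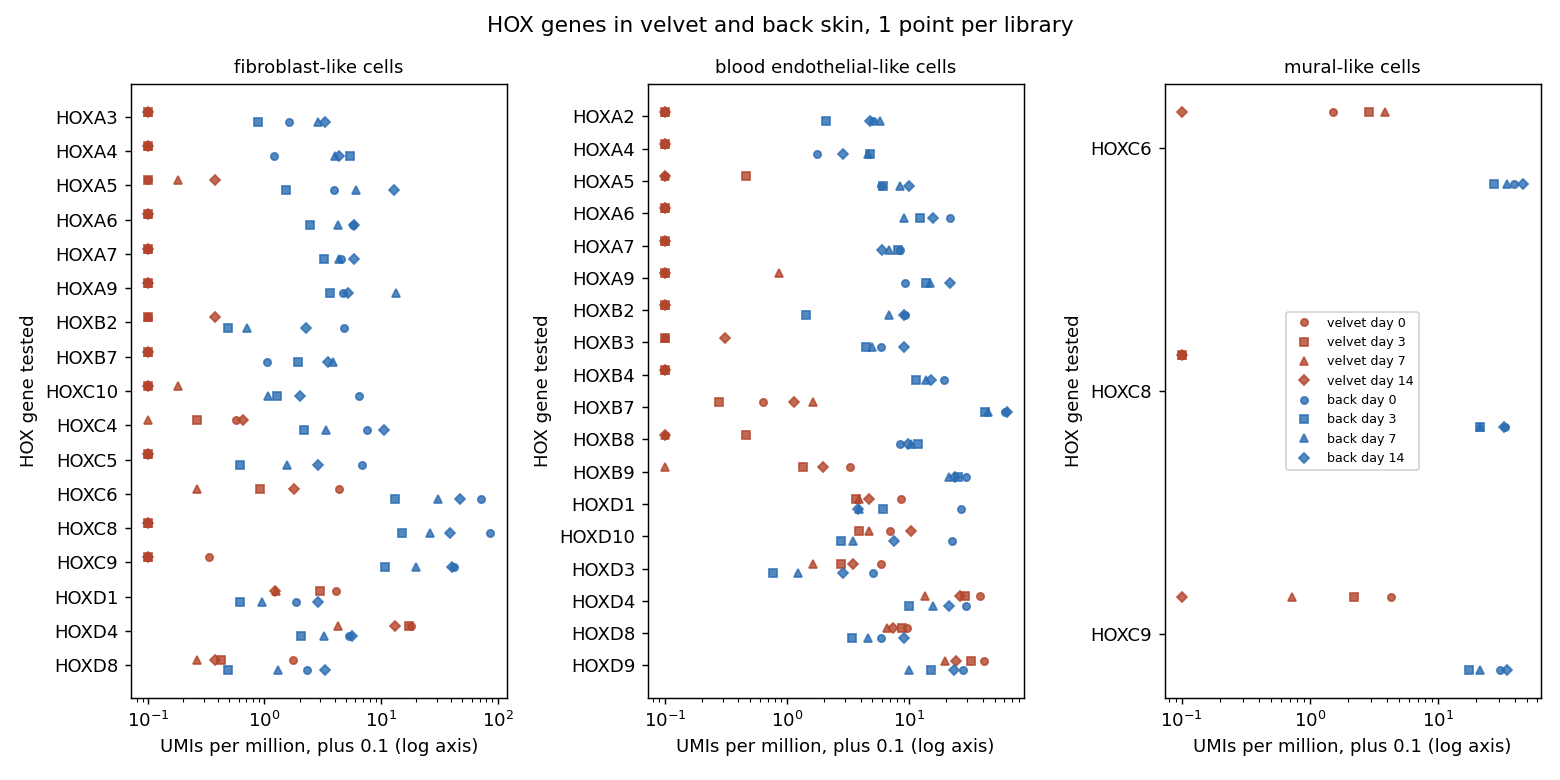
CPM plus 0.1 (log axis, horizontal) of each HOX gene tested in fibroblast-like, blood endothelial-like and mural-like cells (vertical axes), with 1 point per library, red for velvet and blue for back skin, and the marker shape giving the day. HOXC8 sits at 0 in the 4 velvet libraries of fibroblast-like cells, and HOXD4 has 281 velvet against 138 back UMIs there.

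In mural-like cells, 33 of 6898 genes passed in edgeR, 12 higher and 21 lower in velvet. COL8A1 (3.96 ± 0.42), the estrogen receptor ESR1 (3.80 ± 0.47), C11H2orf40 (3.58 ± 0.42), ELN (elastin, 2.82 ± 0.41), MGP (matrix Gla protein, an inhibitor of calcification, 2.57 ± 0.37) and LPL (lipoprotein lipase, 2.26 ± 0.26) were higher. CXCL5 (-5.54 ± 0.75), CD36 (-5.44 ± 0.68), PTGDS (-4.67 ± 0.46), CPE (carboxypeptidase E, -4.66 ± 0.39), CXCL12 (-3.67 ± 0.48) and C7 (-3.66 ± 0.43) were lower, each on 4 of 4 days. Between 9.70% (ESR1) and 46.4% (ELN) of the UMIs of these higher and lower genes lay in the top 1% of cells of the higher tissue. Inflammatory mediators were lower in 4 of 24 (13 adjusted over the list alone; camera adjusted p = 2.49e-11; adjusted p = 0.615 with an estimated correlation), and collagen and elastic matrix genes higher in 2 of 35, COL8A1 and ELN (18 adjusted over the list alone; camera adjusted p = 3.26e-15; adjusted p = 0.615 with an estimated correlation). All 3 HOX genes tested were lower, HOXC6 (-3.93), HOXC9 (-3.87) and HOXC8, with 0 velvet against 83 back UMIs, at least 38.6-fold lower (camera adjusted p = 2.16e-09; adjusted p = 0.562 with an estimated correlation). Contractile genes (0 of 21; camera adjusted p = 0.000133) and the retinoid pathway (0 of 11; 0.0218) tested higher, cell cycle genes (0 of 23; 0.00121) lower, each with adjusted p = 0.66 with an estimated correlation. The complement list (1 of 8 lower; camera adjusted p = 0.0393) and the macrophage inflammatory list (2 of 19 lower; 0.00441) also tested lower (adjusted p = 0.615 and adjusted p = 0.66 with an estimated correlation). The total of 33 genes was 35, 5, 3 and 63 without day 0, 3, 7 or 14. Without day 7 the calls of COL8A1, ESR1, C11H2orf40, ELN, MGP, LPL, CD36, PTGDS, CXCL12 and C7 were lost, without day 3 those of ESR1, C11H2orf40, ELN, MGP, LPL, CXCL5 and CD36, and without day 0 that of ELN.

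In macrophage/monocyte-like cells no gene passed between tissues in edgeR (0 of 10037, with 786 at an unadjusted p under 0.05), and DESeq2 called 44. As lists, cell cycle genes (24 members, 8 higher adjusted over the list alone; camera adjusted p = 2.13e-09), interferon response genes (21, 1 higher; 5e-08) and antigen presentation genes (14, 2 higher; 0.000173) tested higher in velvet (adjusted p = 0.399, adjusted p = 0.399 and adjusted p = 0.418 with an estimated correlation). Inflammatory mediators (29, 3 lower adjusted over the list alone; 0.0165) and the macrophage inflammatory list (30, 1 lower; 0.0155) tested lower (adjusted p = 0.399 and adjusted p = 0.418 with an estimated correlation). TGF-beta (0.00653), collagen (0.0155) and contractile genes (0.0155) tested higher (adjusted p = 0.399 each with an estimated correlation). The members with the smallest p included the antiviral gene RSAD2 (3.51 ± 0.51, adjusted p = 0.13), the replication factor PCLAF (2.29 ± 0.33), the lectin CD209 (-3.44 ± 0.52) and the lysosomal protease CTSD (1.48 ± 0.22), none past the threshold. By day, the median log2 ratio of interferon genes was 1.59, 1.88 and 1.85 at days 0, 3 and 14 and -0.37 at day 7, at percentiles 100, 100, 100 and 0 of random lists. Without day 14, 7 genes passed between tissues. KRT14 was at 333 and 457.8 CPM in velvet macrophages at days 3 and 14 and at 111 and 105 CPM in those of back skin, and clusters of different makeup held the class at day 0.

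Whether the velvet-back difference in fibroblast-like cells changed between uninjured skin and wounds was tested by an interaction term. No gene passed in edgeR (0 of 12776, with 1087 at an unadjusted p under 0.05), and DESeq2 called 50. IGFBP3, an IGF-binding protein, had the smallest adjusted p (4.35 ± 0.48, adjusted p = 0.15). Cell cycle genes tested lower (30 members; camera adjusted p = 0.000218), and inflammatory mediators, WNT and growth factor axis genes (each 0.0437) and BMP genes (0.045) tested higher in the interaction, with no member past the threshold (adjusted p = 0.671 for each with an estimated correlation). The erythrocyte check list (HBA, HBB and ALAS2) had a camera adjusted p of 0.333. The haemoglobin gene HBB was at 308.8 CPM in velvet fibroblast-like cells at day 7 and at 4.0 CPM in those of back skin.

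Between uninjured skin and day 3, averaged over both sites, 16 genes were taken by the rule in fibroblast-like cells. CSTA (cystatin A, a protease inhibitor) rose by 8.22 ± 0.38 (edgeR adjusted p = 0.000546), HP by 6.80 ± 0.72, SLPI (an antiprotease of leukocytes and epithelia) by 7.44 ± 1.13, IL1RN (the interleukin 1 receptor antagonist) by 6.85 ± 1.08 and MMP3 (stromelysin) by 5.90 ± 1.06. The serum amyloid genes M-SAA3.2, SAA2 and SAA3, neighbours on chromosome 29 whose reads may be shared, rose by 10.15 ± 0.72, 10.02 ± 1.11 and 9.94 ± 1.82. OTOR (-5.31 ± 0.73), ANGPTL1 (-3.75 ± 0.52), the BMP antagonist CHRDL1 (-3.66 ± 0.69), the microfibril gene MFAP5 (-3.23 ± 0.47), the retinoic acid enzyme ALDH1A1 (-3.12 ± 0.59), COL8A1 (-3.07 ± 0.39), PLXDC1 (-2.88 ± 0.43) and PDGFRL (-2.78 ± 0.52) fell. In edgeR, 327 of 12024 genes passed, 206 higher and 121 lower. Without the clusters held by 1 library, among them cluster 10 (led by MFAP5 and CHRDL1) and cluster 26, 33 genes passed. Of the 16 named genes, SAA3, CSTA, IL1RN, OTOR, MFAP5, ALDH1A1, COL8A1 and PLXDC1 then lost their call. At day 3, SLPI stood at 0.297 UMIs per fibroblast-like cell in velvet and 8.66 in back skin.

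Cell cycle genes rose at day 3 in 16 of 30 (24 adjusted over the list alone; camera adjusted p = 6.12e-16; adjusted p = 0.36 with an estimated correlation). Among them were RRM2 (2.81), CCNB2 (2.93), UBE2C (2.63) and PLK1 (2.13). The macrophage inflammatory list rose in 12 of 28 (22 adjusted over the list alone; camera adjusted p = 1.58e-15; adjusted p = 0.36 with an estimated correlation). Among them were the calgranulins S100A8 (5.21), S100A9 (5.64) and S100A12 (5.20). S100A8, which macrophages carried at 1455 and 1760 CPM in back skin and velvet at day 3, was at 242.5 and 44.9 CPM in fibroblast-like cells there. Hypoxia and glycolysis genes rose in 8 of 23 (12 adjusted over the list alone; camera adjusted p = 1.87e-08; adjusted p = 0.36 with an estimated correlation). Among them were PFKFB3 (2.50), ENO1 (2.57) and PGK1 (2.04). Inflammatory mediators rose in 6 of 36 (12 higher and 6 lower adjusted over the list alone; camera adjusted p = 0.00404; adjusted p = 0.455 with an estimated correlation). These included IL1B (5.88), CXCL8 (5.52), IL6 (4.96) and CSF3 (3.55). Interferon genes rose in 1 of 20, MX2 (3.42; camera adjusted p = 0.000817; adjusted p = 0.36 with an estimated correlation), and proteases in 4 of 28 with MMP1 at 10.36 and MMP9 at 3.87 among them (camera adjusted p = 0.453).

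Collagen and elastic matrix genes fell in 4 of 41 and rose in 1 at day 3 (15 and 3 adjusted over the list alone; camera adjusted p = 0.000478), dissociation genes fell in 3 of 29 (0.000402) and BMP genes in 1 of 21 (0.00245), with adjusted p = 0.455, adjusted p = 0.455 and adjusted p = 0.36 in turn with an estimated correlation. WNT (0 of 32; camera adjusted p = 2.93e-05), fetal-like (0 of 34; 2.93e-05), HOX (0 of 17; 0.00747) and cranial genes (0 of 20; 0.017) tested lower with no member past the threshold (adjusted p = 0.396, adjusted p = 0.36, adjusted p = 0.463 and adjusted p = 0.396 with an estimated correlation). The complement list had 3 higher and 1 lower of 17 (camera adjusted p = 0.391), with a median of -0.89 and a mean of 0.48. The count of 327 genes was 1 without uninjured back skin, 4 without back skin at day 3, 44 without velvet at day 3, 36 and 34 without back skin or velvet at day 7. It was 503 without uninjured velvet, and 550 and 556 without back skin or velvet at day 14. Without uninjured back skin 15 of the 16 named genes did not pass, the exception being CSTA.

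At day 7, 2157 of 12024 genes passed in edgeR, 1032 higher and 1125 lower. SLPI rose by 11.21 ± 1.27, SAA3 by 9.28 ± 1.83, CSTA by 9.09 ± 0.38, TCN1 (a vitamin B12 carrier of neutrophil granules and secretions) by 8.26 ± 0.79, SAA2 by 7.59 ± 1.06, M-SAA3.2 by 7.27 ± 0.73, IL1RN by 6.68 ± 1.08 and the neutrophil attractant CXCL5 by 6.28 ± 1.44. CCL26 (eotaxin 3, -8.86 ± 1.30), MYOC (-8.28 ± 1.16), OTOR (-6.07 ± 0.75), PI16 (-5.71 ± 0.73), FGL2 (-4.93 ± 0.72), CD34 (-4.83 ± 0.99), IGFBP5 (-4.78 ± 0.54) and the coagulation factor gene F13A1 (-4.73 ± 1.01) fell. CD34 and PI16 mark fibroblasts of uninjured connective tissue. Cell cycle genes rose in 28 of 30 (30 adjusted over the list alone; camera adjusted p = 1.27e-16), the macrophage inflammatory list in 16 of 28 (22 adjusted over the list alone; 2.7e-10) and hypoxia and glycolysis genes in 14 of 23 with 1 lower (15 and 2 adjusted over the list alone; 1.15e-06), including LDHA (2.93) and PGK1 (2.67), with adjusted p = 0.356 for each of the 3 with an estimated correlation.

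At day 7, WNT genes fell in 13 of 32 and rose in 1 (17 and 3 adjusted over the list alone; camera adjusted p = 6.7e-05; adjusted p = 0.412 with an estimated correlation). They included DKK3 (-2.73), DKK2 (-3.53) and AXIN2 (-3.01). Fetal-like and dermal development genes fell in 13 of 34 and rose in 1 (16 and 2 adjusted over the list alone; camera adjusted p = 3.09e-05; adjusted p = 0.356 with an estimated correlation). They included TBX15 (-2.67), GLI1 (-4.22) and FREM1 (-4.57). BMP genes fell in 9 of 21 (15 adjusted over the list alone; camera adjusted p = 8.45e-05; adjusted p = 0.356 with an estimated correlation). They included BMP3 (-4.69), BMP7 (-5.42) and CHRDL1 (-4.61). Complement fell in 8 and rose in 3 of 17 (camera adjusted p = 0.013), TGF-beta fell in 10 and rose in 2 of 28 (0.013), growth factor axis genes 12 and 2 of 35 (0.0119), angiogenic factors 9 and 2 of 24 (0.0348), collagens 13 and 3 of 41 (0.0228), cranial genes 3 and 0 of 20 (0.0208) and dissociation genes 5 and 0 of 29 (0.011). With an estimated correlation these gave adjusted p-values from 0.356 to 0.688. Examples were C7 (-3.51), IGFBP2 (-4.29), IGF2 (-4.23), ELN (-3.39) and MFAP5 (-3.76), with HP (4.36) and HIF1A (2.62) higher. The inflammatory, contractile, protease, retinoid, interferon and resolution lists had members both ways (6 and 7, 5 and 3, 6 and 3, 3 and 5, 1 and 3, and 4 and 6 higher and lower) and camera adjusted p-values from 0.102 to 0.904. The count of 2157 was 68 and 145 without velvet or back skin at day 7, 162 without uninjured back skin, and 1231 and 1229 without velvet or back skin at day 3. Without velvet at day 7 the named genes other than SLPI, CSTA, TCN1, SAA2 and M-SAA3.2 no longer passed, and 9 of the 16 did not without back skin at day 7. Without uninjured back skin SLPI, SAA3, IL1RN, MYOC, FGL2 and F13A1 did not.

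At day 14, 58 of 12024 genes passed in edgeR, 43 higher and 15 lower. SLPI (11.69 ± 1.28), M-SAA3.2 (9.31 ± 0.72), CSTA (8.46 ± 0.38), SAA2 (8.42 ± 1.06), TCN1 (8.40 ± 0.80), the gelatinase MMP9 (6.99 ± 0.60), UCHL1 (6.60 ± 0.60) and S100A9 (6.29 ± 0.52) were higher than in uninjured skin. CCND1 (cyclin D1, -2.87 ± 0.35), ENTPD2 (-2.65 ± 0.33), TM4SF1 (-2.23 ± 0.27), DPEP1 (-2.18 ± 0.32), EMID1 (-2.13 ± 0.32), FXYD6 (-2.11 ± 0.27) and TRIM47 (-1.83 ± 0.26) were lower. Interferon genes were higher in 2 of 20, IFIT1 (2.10) and MX2 (4.42; 9 higher and 1 lower adjusted over the list alone; camera adjusted p = 1.56e-05; adjusted p = 0.478 with an estimated correlation). The macrophage inflammatory list was higher in 3 of 28, the genes S100A8, S100A9 and S100A12 (7 higher and 1 lower adjusted over the list alone; camera adjusted p = 4.4e-05; adjusted p = 0.48 with an estimated correlation). Cell cycle genes had no member past the threshold over all genes and 17 of 30 higher adjusted over the list alone (camera adjusted p = 5.56e-09; adjusted p = 0.48 with an estimated correlation), and dissociation genes tested lower (0 of 29; camera adjusted p = 4.93e-05; adjusted p = 0.48 with an estimated correlation). Contractile (camera adjusted p = 0.0064) and hypoxia genes (0.0198) tested higher, and BMP (0.0064), TGF-beta (0.00729), angiogenic (0.0183), complement (0.0245), fetal-like (0.029), WNT (0.031), cranial (0.0317) and growth factor axis genes (0.0355) lower. With an estimated correlation all 10 gave adjusted p-values from 0.478 to 0.593. Single members past the threshold among these lists were C7 (-4.15) lower and TGFBI (3.53) and HIF1A (2.24) higher. The count of 58 was 1 without uninjured back skin, 29 without back skin at day 14, 26 and 28 without back skin or velvet at day 3, 26 and 28 without back skin or velvet at day 7, and 430 without uninjured velvet. CCND1, TM4SF1, DPEP1, EMID1, FXYD6 and TRIM47 did not pass in 7 of the 8 refits without a single library, and 14 of the 15 named genes did not without uninjured back skin.

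**Figure D4:**
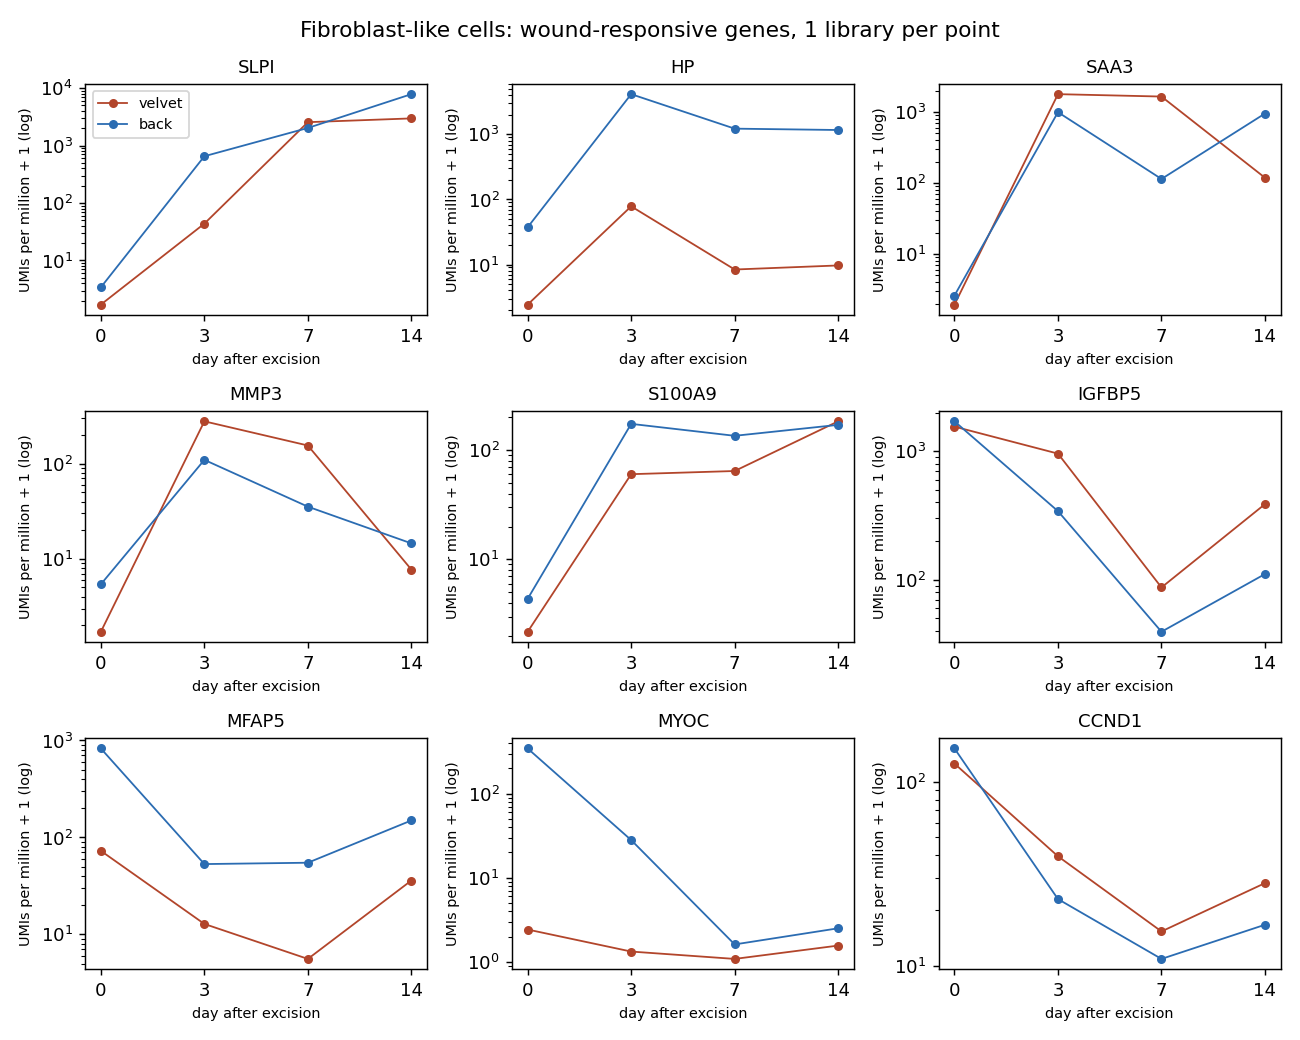
CPM plus 1 (log axis, vertical) of 9 genes named between days in fibroblast-like cells, against day after excision (horizontal axis), for velvet (red) and back skin (blue), with 1 library per point. HP reaches 4160 CPM in back skin and 77.4 CPM in velvet at day 3.

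In macrophage/monocyte-like cells, 10 genes were taken by the rule at day 3. MMP9 (6.22 ± 0.81), TNIP3 (an inhibitor of NF-kB signalling, 5.90 ± 0.52), the aggrecanase ADAMTS5 (5.23 ± 0.82), CCL20 (4.89 ± 0.74) and TCN1 (4.84 ± 0.69) rose. BRB (brain ribonuclease, -9.95 ± 1.23), the iron exporter SLC40A1 (-4.43 ± 0.69), C1QB (-3.92 ± 0.48), RGS1 (-3.34 ± 0.47) and C1QA (-3.34 ± 0.42) fell. In edgeR 116 of 10037 genes passed, 53 higher and 63 lower. The macrophage inflammatory list rose in 5 of 30 (18 higher and 1 lower adjusted over the list alone; camera adjusted p = 6.68e-08), including CXCL5 (4.71), TNF (3.71) and IL1A (3.17), inflammatory mediators rose in 4 of 29 (1.58e-06), and resolution and tissue resident genes fell in 5 of 29 (16 lower and 4 higher adjusted over the list alone; 0.000268), including C1QC (-2.93) and STAB1 (-2.39), with adjusted p = 0.428 for each of the 3 with an estimated correlation. Collagens were lower in 2 of 26 (camera adjusted p = 0.0384) and hypoxia genes tested higher with 0 of 22 (0.0409), with adjusted p = 0.602 and adjusted p = 0.747 with an estimated correlation. The 2 were the fibroblast transcripts COL1A1 (-1.90) and COL1A2 (-1.91). COL1A1 also went from 95.7 to 17.6 CPM in T and NK-like cells of back skin and from 70.9 to 44.1 CPM in those of velvet, while the fibroblast-like share of back cells went from 38.8% to 9.94%. Different clusters held the class at day 0 and day 3, cluster 33 or 11 before injury and the IL1B-led cluster 3 after it. The count of 116 was 0 without uninjured back skin and without back skin at day 3, 1 without velvet at day 3, 73 without velvet at day 7, 252 without uninjured velvet, and 368 and 380 without velvet or back skin at day 14. The 10 named genes did not pass in the first 3 of these. With only the clusters led by class markers, 26 genes passed, and of the 10 named genes TNIP3, ADAMTS5, CCL20, SLC40A1, C1QB and C1QA did not. CCL20 and TCN1 did not pass without cluster 33.

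At day 7, 10 genes passed in these cells in edgeR (1 higher and 9 lower, of 10037). Since day 0 cluster 3 had gone from 27.8% to 60.6% of the class in velvet and 5.74% to 62.8% in back skin. The rule took TNIP3 (5.14 ± 0.51, adjusted p = 0.0168), a leading gene of that cluster. It did not pass in the first clustering version (2.18, adjusted p = 0.127), at the doubled resolution (2.50), with only the clusters led by class markers (1.42) or with a mean of at least 20 CPM (5.10). Over all alternatives its adjusted p ran from 4.64e-13 to 0.228. The macrophage inflammatory list (14 higher and 1 lower adjusted over the list alone; camera adjusted p = 1.14e-05) and inflammatory mediators (0.000189) tested higher and resolution genes lower (0.0141), with adjusted p = 0.558 for each with an estimated correlation. At day 14, 7 genes passed (3 higher and 4 lower), with GNG11 (4.95 ± 0.53), the macrophage elastase MMP12 (4.61 ± 0.57) and CTSD (3.35 ± 0.34) higher. All 3 lost their call with equal cells per library. MMP12 is among the leading genes of cluster 11, which held 13.9% of the class in uninjured back skin and 62.5% at day 14, and 66.0% and 73.3% in velvet. Interferon genes tested higher (camera adjusted p = 0.00015; adjusted p = 0.508 with an estimated correlation), and collagen (0.000381) and dissociation genes (0.000405) lower (adjusted p = 0.369 for both with an estimated correlation). The collagen members with the smallest p, DCN (-1.83), LOX (-6.86), ASPN (-3.64) and COL1A2 (-1.23), are genes of fibroblasts, and none passed. Inflammatory (0.00706), growth factor axis (0.0258), TGF-beta, macrophage inflammatory and resolution (each 0.0281), hypoxia (0.0366) and angiogenic genes (0.0371) also tested lower (adjusted p = 0.369 to adjusted p = 0.684 with an estimated correlation). The counts of 10 and 7 were both 0 without uninjured back skin. The day 7 count was 0 without velvet at day 3 or 7 or back skin at day 3, 2 without back skin at day 7, 127 without uninjured velvet, and 154 and 164 without velvet or back skin at day 14. The day 14 count was 1 without velvet or back skin at day 3, 49 without uninjured velvet, and 48 and 80 without velvet or back skin at day 14.

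Within single days the libraries can be set side by side but not tested. In uninjured fibroblast-like cells, velvet over back ratios of CPM were 158 for CA3 (95% exact Poisson interval 75.8 to 396), 66.2 for PTN and 36.7 for APOA1 (0.286 under the stricter cell filter), and back over velvet ratios 4411 for PTGDS (from 2 velvet UMIs, 1221 to 36426), 521 for CXCL5 (1 velvet UMI) and 243 for MYOC. At day 3, back over velvet ratios were 53.7 for HP (49.1 to 58.9) and 53.9 for PTX3 (46.4 to 62.9), a pattern recognition protein, and velvet over back ratios 77.5 for SST and 25.7 for the WNT inhibitor WIF1. At day 7, HP was 166-fold higher in back skin (135 to 207), while OXT (oxytocin) was 214-fold higher in velvet and the haemoglobin genes HBA, HBB and HBG 110-, 76.8- and 68.4-fold. At day 14, PTN was 346-fold (242 to 514) and OMD (osteomodulin) 193-fold higher in velvet, ALX1 at least 62.1-fold, and HP 135-fold higher in back skin (94.8 to 198).

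Among macrophage/monocyte-like cells of uninjured skin, S100A9 was 13.2-fold (11.3 to 15.6) and IL6 10.2-fold higher in velvet. FOLR3, CCL24 and LYVE1, leading genes of cluster 33, were 408-, 81.4- and 21.5-fold higher in back skin. That cluster held 80.4% of the class in uninjured back skin and 6.19% in uninjured velvet. At day 3 the melanocyte gene PMEL was 164-fold and PTGDS 32.8-fold higher in velvet macrophages, and CSF3 12.1-fold and the metallothionein MT2A 8.08-fold higher in those of back skin. At day 14 the interferon genes RSAD2, ISG20 and IFIT2 were 25.1-, 22.5- and 19.2-fold higher in velvet, beside KRT1 at 25.5-fold, and SAA3 was 83.0-fold higher in back skin. In endothelial cells, COL8A1 was 167-fold and CXCL10 75.2-fold higher in velvet at day 3, beside KRT1 at 19.1-fold and S100A7 at 23.5-fold. In mural cells, MMP3 was at least 34.9-fold higher in velvet at day 3 and 190-fold at day 7, and CXCL5 was 273-fold higher in back skin before injury and 128-fold at day 14.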

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

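The tests of the clusters held by 1 library, named in this part, were chosen after the results were seen. The tests of free RNA had their thresholds written before their values were computed, a ratio of at most 1.5 for free RNA and of at least 3 against it. The ratio was a median over genes and libraries, and for HOX genes the lowest over libraries and both classes. The reference in each is the median of the levels of 3 other classes of the same library, with a floor of 3 counts per class.

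PTGDS was singled out because the CPM of every wound library lay above the uninjured library in velvet and below it in back skin. In fibroblast-like cells the mean log2 CPM of wound days minus day 0 was 0.55 in velvet and -4.28 in back skin, a difference of 4.83 whose means were not tested. Velvet held 2 UMIs of PTGDS at day 0, so its change there rests on few counts. In back skin the gene leads cluster 26, which had 562 of its 600 cells from uninjured back skin, and its tissue call was lost without the clusters held by 1 library. CXCL3 was singled out in the same way, at 1.253 in velvet and -0.67 in back skin, a difference of 1.92 whose means were not tested. The edgeR term for the tissue difference in wounds against uninjured skin, fitted on these 8 libraries, gave 5.82 ± 1.12 for PTGDS (adjusted p = 0.365) and 1.99 ± 0.78 for CXCL3 (adjusted p = 0.563). AMIGO2 in blood endothelial-like cells went the other way, at -1.34 in velvet and 1.247 in back skin, a difference of -2.59 that was not tested.

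The next 3 groups of cells, which entered no main test of genes, stood above their level in uninjured skin. Unnamed cluster 0, led by CATHL3 and TNFSF14 and closest to neutrophils, reached 43.9% of cells in velvet at day 7. The 95% exact interval of its share lay above those of both uninjured libraries in 5 of 6 wound libraries, and the share itself in all 6. Unnamed cluster 7, led by SPP1, S100A12 and MMP9, reached 9.61% in velvet at day 7, with intervals above them in 6 of 6. Unnamed cluster 14, led by defb402, LAP and IL23A, reached 11.3% in back skin at day 3, with intervals above them in 5 of 6 and the share itself in all 6.

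The acute phase, antiprotease and calgranulin genes higher in wound fibroblast-like cells are genes that neutrophils and epithelia also express, so free RNA taken up in droplets was weighed first. Over 13 genes and 6 wound libraries, the median UMIs per fibroblast-like cell were 25.9 times those per T and NK-like, mast-like or lymphatic endothelial-like cell, which argues against free RNA for the set. Medians by gene ran from 1.69 for IL1RN to 350 for SLPI, with 4.08 for the calgranulin S100A9. The calgranulins S100A8 and S100A12 were not among the 13 genes. In single libraries 18 of the 78 ratios lay under 3, so free RNA stays open for all 6 of IL1RN (median 1.69), 3 of MMP9 (1.01 in velvet and 1.81 in back skin at day 3), S100A9 in velvet at days 3 and 14 (1.71 and 1.51), TCN1 at day 3 (2.07 and 2.37) and 1 each of HP (2.66 in velvet at day 7), CXCL5, M-SAA3.2, MMP3 and UCHL1. Doublets with neutrophils and a change in which fibroblast clusters were caught, with cluster 22 at 58.0% of the class in velvet at day 7 and 0% before injury, were not tested apart. A response of fibroblasts to wounding, which the design names, stays open as a hypothesis.

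The inflammatory genes lower in velvet fibroblast-like cells (6 genes, among them HP, CSF3, TNFAIP6, CCL20 and CXCL3) stood in back libraries at a median of 24.8 times their level in the 3 reference classes, which argues against free RNA for the set. For CCL20 the ratio was 0.969, 2.68, 2.76 and 5.88 at days 0, 3, 7 and 14, so free RNA stays open for that gene at days 0, 3 and 7. Without the clusters of which 1 library held over 80% of the cells, the median log2 fold change of the 6 genes went from -3.80 to -2.56, or 67.5% of its size, between the bounds of 25% and 75% set for that test. How far those clusters are a state of back skin fibroblasts or a trait of 1 library cannot be told apart with 1 library per tissue and day. A lasting difference between the tissues stays open and was not tested.

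The HOX genes lower in velvet endothelial-like and mural-like cells were weighed against free RNA from fibroblasts, which also carry HOX genes. In back libraries the lowest ratio of summed HOX UMIs per endothelial-like or mural-like cell to those per T and NK-like, mast-like or macrophage/monocyte-like cell was 5.03, in endothelial-like cells at day 14, and the highest was 120, in mural-like cells at day 14. That argues against free RNA as the whole of these HOX counts. In back skin at days 0, 3, 7 and 14, endothelial-like cells held 0.435, 1.53, 1.53 and 1.36 UMIs of their called HOX genes each. Fibroblast-like cells held 0.082, 0.149, 0.671 and 0.356 of those, which argues against them as the source there. Mural-like cells held 0.329, 0.84, 1.12 and 0.967 UMIs of theirs. Fibroblast-like cells held more of those at days 0, 7 and 14 (0.854, 1.75 and 1.46) and less at day 3 (0.519). In the same libraries HOXD4 was not lower in velvet, with 281 against 138 UMIs in fibroblast-like and 388 against 174 in endothelial-like cells. A positional difference between head and trunk skin stays open as a hypothesis and was not tested, which HOX counts from head skin away from the antler would do.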

How the results depend on the processing

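The first clustering version, leaving out the clusters held by 1 library and the 2 other makeups of the macrophage/monocyte class were tests chosen after the results were seen. No paired analysis was possible because the labels carry no replicate numbers, so velvet and back libraries were matched only by day, as a covariate in the fits and as day pairs in the test of shares. With 1 library per tissue and day, leaving out a library in a day contrast leaves 1 library for that day, which is assumed to vary like the others. The interaction could not be fitted without day 0. Unless a setting's construction shows it, the cause of a change was not tested. Of 1813 values of 107 gene results under alternatives, 1443 kept direction and threshold, 370 kept only the direction and 0 reversed. The rule took calls with the same direction on every day or in both tissues, so a reversal was unlikely. Of 189 gene counts, 75 stayed within 1.5 times. Of 486 list values, 313 stayed on the same side of the threshold, 172 lost it and 1 gained it. Those 313 include every list that passed in neither test, direction not compared, so they are not all calls that held. Of 768 values of single-day ratios, 671 stayed within their interval, 96 moved and 1 reversed. Of 85 class share values, 78 kept their sign. RLE normalization moved no gene count by over 1.5 times (359 genes between tissues in fibroblast-like cells). On counts simulated at the depth of these libraries, all 4-fold changes were called in each class and between 16 and 25 of 50 2-fold changes. Small changes can therefore be missed at this depth and number of libraries. Changed genes had a mean of at least 20 CPM and the trend's spread at their level. Genes that vary more can be missed at larger changes. RSAD2 in macrophage/monocyte-like cells was fitted at over 4-fold and did not pass.

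The values as reported were 366 genes between tissues in fibroblast-like cells, 327, 2157 and 58 at days 3, 7 and 14 and 0 in the interaction. They were 0 between tissues and 116, 10 and 7 by day in macrophage/monocyte-like cells, 55 in blood endothelial-like and 33 in mural-like cells. The 0 counts are edgeR's, with 1087 (interaction) and 786 (macrophage/monocyte tissue) genes at an unadjusted p under 0.05.

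The DESeq2 Wald test called 860, 1142 and 582 genes in fibroblast-like cells (tissue, day 3, day 14) and 50 in the interaction. It called 44, 462, 257 and 180 in macrophage/monocyte-like cells (tissue, days 3, 7 and 14), 174 in endothelial-like and 93 in mural-like cells. With no filter beyond 1 UMI the counts were 693, 843, 408 and 19 in fibroblast-like cells (tissue, day 3, day 14, interaction). They were 105, 595, 365 and 250 in macrophage/monocyte-like, 227 in endothelial-like and 324 in mural-like cells. With a mean of at least 20 CPM, which tests fewer genes, they were 108, 153, 1004 and 31 in fibroblast-like cells (tissue, days 3, 7 and 14). They were 42, 0 and 1 in macrophage/monocyte-like cells (days 3, 7 and 14), 5 in endothelial-like and 19 in mural-like cells.

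The stricter cell filter gave 579 and 116 genes in fibroblast-like cells at days 3 and 14, and 1 and 39 in macrophage/monocyte-like cells (tissue, day 7). With doublet calls kept, fibroblast-like cells gave 33 at day 14 and macrophage/monocyte-like cells 50 and 11 at days 7 and 14. The doubled clustering resolution gave 5, 183, 63 and 60 in macrophage/monocyte-like cells (tissue, days 3, 7 and 14). The first clustering version gave 4, 35 and 37 there (tissue, days 7 and 14). Equal cells per library, which lowers the counts, gave 156 at day 3 in fibroblast-like cells, 26, 3 and 1 in macrophage/monocyte-like cells at days 3, 7 and 14, and 11 in mural-like cells.

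Without the clusters held by 1 library, fibroblast-like cells gave 90, 33 and 137 genes (tissue, days 3 and 14) and macrophage/monocyte-like cells 2 and 12 (tissue, day 14). With only marker-led clusters, macrophage/monocyte-like cells gave 2, 26, 34 and 53 (tissue, days 3, 7 and 14), and with the close unnamed clusters 42 and 11 at days 7 and 14. With no day covariate the tissue counts were 19 in fibroblast-like, 28 in endothelial-like and 7 in mural-like cells.

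Leaving out 1 day pair at a time gave between 68 and 198 genes in fibroblast-like cells, 0 and 7 in macrophage/monocyte-like, 1 and 40 in endothelial-like and 3 and 63 in mural-like cells. The interaction gave 0 throughout (edgeR). Leaving out 1 library at a time gave 1 to 556, 68 to 2552 and 1 to 430 genes in fibroblast-like cells at days 3, 7 and 14. In macrophage/monocyte-like cells it gave 0 to 380, 0 to 164 and 0 to 80. Each lowest value came without uninjured back skin, except at day 7 in fibroblast-like cells, where it came without velvet at day 7. In macrophage/monocyte-like cells 0 genes also came without back skin at day 3 (days 3 and 7) and without velvet at days 3 or 7 (day 7).

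Camera with an estimated correlation passed 0 lists in each of the 11 comparisons. The main camera test had passed 11, 12, 13 and 14 lists in fibroblast-like cells (tissue, days 3, 7 and 14), 5 in the interaction, 8, 5, 3 and 10 in macrophage/monocyte-like, 6 in endothelial-like and 8 in mural-like cells. The fry test passed 3, 4, 6 and 0 in fibroblast-like cells, 0 in the interaction, 2, 0, 0 and 1 in macrophage/monocyte-like, 2 in endothelial-like and 1 in mural-like cells.

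Among shares, the macrophage/monocyte mean logit difference of -0.90 was -0.63 in the first clustering version, -0.43 with only marker-led clusters and -0.50 without the clusters held by 1 library. The fibroblast-like value reversed from -0.48 to 0.17 without those clusters. The T and NK-like mean logit difference reversed from -0.43 to 0.21 with immune cells as the denominator. The mural-like value reversed from 0.03 to -0.00234 at the doubled resolution and to -0.186 with a non-immune denominator, and ran from -0.0605 to 0.182 when 1 day pair was left out, with -0.0542 without day 7. The lymphatic value ran from -0.968 to 0.0568. The fibroblast APOA1 ratio at day 0 reversed from 36.7 to 0.286 under the stricter filter.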

Other observations

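The counts over other splits of the libraries, at the end of this part, were tests chosen after the result was seen. Clusters of hair and gland cells entered no gene test, and their shares were not tested. Cluster 19, led by the hair keratins KRT85, KRT35 and KRT31, made up 6.94%, 3.57%, 0.534% and 2.70% of velvet cells and 1.99%, 0.0518%, 0.0878% and 0.846% of back cells at days 0, 3, 7 and 14. Cluster 25, led by the inner root sheath keratins KRT25, KRT27 and KRT28, made up 3.88%, 0.822%, 0.147% and 1.28% of velvet and 2.10%, 0.0690%, 0% and 1.08% of back cells. Cluster 30, led by MOGAT3 and other lipid enzyme genes of sebaceous type, made up 3.27% of uninjured velvet and 0.474% of uninjured back skin. Cluster 13, a keratinocyte-like cluster led by genes that include KRT75 and KRT17, made up 3.99%, 2.07%, 0.626% and 5.47% of velvet and 5.91%, 0.604%, 0.0878% and 0.885% of back cells. These shares follow a dispase step meant to remove epidermis.

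Cluster 32, led by the pigment genes PMEL and TYRP1, was mostly from uninjured back skin (141 of 197 cells). Cluster 31, led by JCHAIN and MZB1, genes of antibody-secreting cells, was absent from uninjured back skin and made up 1.75% of velvet and 1.49% of back cells at day 7. Cluster 36, led by CSF3 and CCL3, had 112 of its 130 cells from back skin at day 3 and the other 18 from back skin at day 7. Cluster 37, a keratinocyte-like cluster led by the interferon genes IFIT1, IFIT2 and ISG15, had 33 of its 59 cells from velvet at day 3.

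Interferon response genes were set side by side on each day. In fibroblast-like cells their median log2 ratio of velvet over back was 0.99, 0.82, -0.27 and 0.68 at days 0, 3, 7 and 14, at percentiles 99.8, 99.9, 0.34 and 97.7 of random lists. In blood endothelial-like cells it was 0.63, 2.05, -0.39 and 0.29, at percentiles 99.4, 100, 0.01 and 97.0. In mural-like cells it was 1.15, 0.80, 0.36 and -1.27, at percentiles 99.95, 99.7, 75.3 and 0.02. Members that move together can give percentiles near 0 or 100 from 1 shared shift between 2 libraries. Whether day 7 or day 14 differs from the other days was not tested.

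The 8 libraries were divided in other ways that also put the libraries of every day into different groups, which gives 8 splits with the real one. That is too few for a share under 0.05. Fibroblast-like cells gave 366 genes in the real split and at most 1 in the others, so 1 split gave as many. Blood endothelial-like cells gave 55 and at most 0, and mural-like cells 33 and at most 0, again with 1 split as large. Macrophage/monocyte-like cells gave 0 genes with edgeR in the real split, where 786 had an unadjusted p under 0.05 and DESeq2 called 44. The other splits gave at most 1, so all 8 splits gave as many. Any split reaches a count of 0, so this comparison could not tell the real split from the others.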
